A study of Homo sapiens with 6 samples.

How the data were processed

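Poly-A selected RNA of Kasumi-1 cells had been sequenced as paired-end reads on an Illumina NovaSeq instrument, per the labels' protocols, in 3 libraries with a non-targeting hairpin and 3 with hairpin RNA against HASPIN. The descriptions give the 3 knockdown libraries the same sh tag, which the labels do not explain, so the comparison may rest on 1 hairpin. Cells were kept in 1.0 µg/ml puromycin after transduction, and RNA was taken 4 days after selection, per the labels' protocols. STAR 2.7.10a, SAMtools 1.10, featureCounts 2.0.0 and the build hg38 are named in the submitters' processing notes. The annotation release, the strand setting and the treatment of reads that match several genes are not given in the sources used here. The hairpin sequences are likewise not given in the sources used here. The table holds 60308 genes by symbol, and 27345 of them are 0 in all 6 libraries.

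The deposited values are a normalised signal, gene counts divided by 1 factor per library. Within each library 100% of the non-zero values were whole multiples of the smallest non-zero value, within a tolerance of 0.001, so whole reads per gene were recovered, on which edgeR called 1421 genes rising and 1507 genes falling. The factors were 1.05, 0.985 and 0.956 for shCTRL replicates 1, 2 and 3 and 1.05, 0.915 and 1.15 for the shHASPIN replicates, and they equal median-of-ratios size factors recomputed from the recovered reads. This scaling assumes that most genes do not change, so a shift of all genes together would not be seen. Recovered reads ranged from 63365042 to 72808618 per library. The reads carry no molecular identifiers, so copies made in amplification count as reads, and intervals from counts would cover counting error only.

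Groups and replicate numbers were taken from the sample titles. The tests, alternatives and gene lists were fixed before the data were examined. The main test was limma 3.58.1 (moderated, with a mean-variance trend) on log2(deposited value + 1), for the 19482 genes with a mean of at least 10 over the 6 libraries, with Benjamini-Hochberg adjustment and a threshold of 0.05. HASPIN was also tested by a two-sided exact permutation test. The samples of the same number were not treated as pairs. Gene lists, 36 in number and drawn from textbook knowledge, were tested with camera in limma at a small preset correlation between genes, and again with a correlation estimated for each list. With the estimated correlation camera called 0 of the 36 lists, and 3 had an unadjusted p under 0.05. Symbols were matched to GENCODE 29 for 18891 (97.0%) of the tested genes, and 13263 tested genes were protein-coding.

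Genes were named by a rule. It took HASPIN, all measured SR proteins and BCL-2 family members, and the 12 rising and 12 falling protein-coding genes with the largest change that passed, had a mean of at least 100 in the higher group and no overlap between groups. It also took up to 4 members of each list past the threshold, by p in the direction of the list, and up to 2 of each other list. Genes outside the rule are marked as named after their values were seen, and some genes that the rule took are not reported here.

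Alternatives were other pseudocounts, no filter and a stricter filter, equal library totals, quantile normalisation, no mean-variance trend, the replicate number as a block, each library left out in turn, ranks in camera, edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 on the recovered reads. A fit of GC content and transcript length in each library, and shCTRL replicate 1 as the only control, were added after the data were seen. Counts drawn from the real means and dispersions, with 200 changed genes of a mean of at least 50 in each of 5 runs over 19482 genes, were used to test the limma step on simulated data. Of genes changed 1.5-, 2-, 4- and 8-fold it recovered 18.0%, 64.8%, 89.2% and 98.8%, and 6.75% of its calls were false, so small changes were often missed there. The real comparison called 3045 genes, more than the 200 simulated changes, and the adjusted threshold depends on that number. The shares recovered in the real data are therefore not known.

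For the word scan the fold changes of 11569 genes with a mean of at least 50 and an annotated 3' UTR (GENCODE 29) were limited to 3 in either direction and fitted on 3' UTR length and GC content. The remainder was then averaged over the genes holding each word of 7 bases, as a z value, for the 15529 words found in at least 100 genes. The genes were shuffled 100 times to give the lowest z that chance reached. On simulated data the scan ranked 3 of 3 implanted words lowest, with a fall of 0.4 on the log2 scale in every gene holding the word. The real genes holding TGTATTTA had a mean remainder of -0.186, and falls as small as this were not simulated. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, matplotlib 3.10.9 and R 4.3.3 were used. Exon usage and splice junctions were not analysed here.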

Results

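RNA was measured in Kasumi-1, a human acute myeloid leukaemia cell line that carries the RUNX1-RUNX1T1 fusion gene. The cells had been transduced with a non-targeting control hairpin (shCTRL) or with hairpin RNA against HASPIN (shHASPIN), a kinase that phosphorylates histone H3 in mitosis. There were 3 libraries per group, from RNA taken 4 days after puromycin selection. Whole reads recovered from the deposited values came to 68880032, 70038118 and 65129389 in shCTRL replicates 1, 2 and 3, and to 71552184, 63365042 and 72808618 in the shHASPIN replicates. Reads were found for 27443, 22266 and 22356 genes in the shCTRL replicates and for 27245, 25071 and 27076 genes in the shHASPIN replicates, so shCTRL replicates 2 and 3 detected fewer genes than the other 4 libraries. The number of genes with 5 reads, per gene with 1 read, was 1.29 and 1.57 in those 2 libraries. It was 0.547 in shCTRL replicate 1 and 0.582, 0.641 and 0.700 in shHASPIN replicates 1, 2 and 3. The labels do not say that replicates were separate cultures, so p-values measure the spread between these samples, which may be technical.

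**Figure D1:**
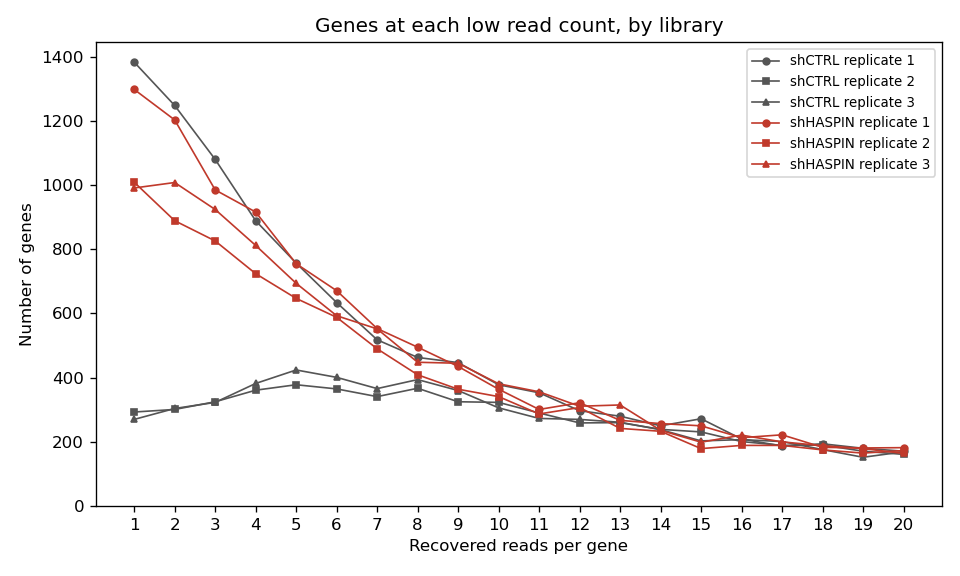
Number of genes (vertical axis) at each recovered read count from 1 to 20 (horizontal axis), with 1 line per library, grey for shCTRL and red for shHASPIN. The curves of shCTRL replicates 2 and 3 start at 293 and 270 genes with 1 read, against 1383 genes in shCTRL replicate 1 and 1298, 1009 and 991 genes in the shHASPIN replicates.

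HASPIN, the targeted gene, was reported first because it checks the labels. Its normalised read count was 839, 1209 and 1234 in shCTRL replicates 1, 2 and 3, and 441, 599 and 639 in shHASPIN replicates 1, 2 and 3. The mean fell by 48.8%, from 1094 ± 221 (SD, n = 3) to 559.8 ± 104 (SD, n = 3), and every shHASPIN library lay below every shCTRL library. The log2 fold change was -0.96 with a standard error of 0.21 (limma adjusted p = 0.0115). The two-sided exact permutation test gave p = 0.1, the smallest value that 3 against 3 libraries allow. HASPIN has 1 exon on the plus strand of chromosome 17, positions 3723903 to 3726699 (GRCh38, GENCODE 29). It lies inside the integrin gene ITGAE, which runs on the minus strand from 3714628 to 3801243, and 0 ITGAE exons overlap it. Whether the counting used strand is not given in the sources used here, so reads from unspliced ITGAE RNA cannot be separated from HASPIN reads. ITGAE, named after its value was seen, also fell, from 807 ± 126 (SD, n = 3) to 497 ± 45.0 (SD, n = 3), to 61.7% of control (log2 fold change -0.69, limma adjusted p = 0.0289). The limma call on the HASPIN transcript level was lost without shCTRL replicate 3 (log2 fold change -0.86, adjusted p = 0.0613), without shHASPIN replicate 1 (-0.80, adjusted p = 0.0519) and without the mean-variance trend (adjusted p = 0.0754). It was also lost against shCTRL replicate 1 alone (-0.60, adjusted p = 0.179), with a range of adjusted p over all alternatives from 0.000252 to 0.179.

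Across the transcriptome, genes moved in both directions between the group means, while the control libraries differed among themselves in low genes. Over the tested genes shCTRL replicate 1 correlated more closely with shHASPIN replicates 1, 2 and 3 (r = 0.968, 0.963 and 0.964) than with shCTRL replicates 2 and 3 (0.954 and 0.961), which correlated with each other at 0.945, and the shHASPIN replicates correlated with each other at 0.973 to 0.981. Genes with a mean of 10 to 100 carried this: the SD of the log2 difference from shCTRL replicate 1 was 1.71 and 1.61 in the other controls and 1.21, 1.35 and 1.27 in shHASPIN, against 0.47 and 0.33 and then 0.52, 0.56 and 0.54 at a mean of at least 1000. On the first principal component, with 42.2% of the variance, shCTRL replicate 1 lay at -0.17, the other controls at -99.3 and -67.3, and the shHASPIN replicates at 59.0, 47.6 and 60.2. STAB1, a scavenger receptor, rose from 30.9 ± 4.07 (SD, n = 3) to 3385 ± 1002 (SD, n = 3), a log2 fold change of 6.70 ± 0.25 (SE; limma adjusted p = 2.89e-07). KLF2, a Krüppel-like transcription factor, rose from 39.5 ± 32.0 (SD, n = 3) to 2855 ± 859.7 (SD, n = 3), a log2 fold change of 6.38. ANAPC13, a subunit of the anaphase-promoting complex, fell from 3463 ± 30.6 (SD, n = 3) to 720.3 ± 30.3 (SD, n = 3), a log2 fold change of -2.26 ± 0.14 (SE; limma adjusted p = 1.83e-05). STAB1 lies on chromosome 3, positions 52495338 to 52524495, KLF2 on chromosome 19, positions 16324817 to 16327874, and ANAPC13 on chromosome 3, positions 134477706 to 134486716 (GRCh38, GENCODE 29).

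Of 19482 genes tested with limma, 1515 rose and 1530 fell at an adjusted p under 0.05, together 15.6% of the genes, and 5833 had an unadjusted p under 0.05. A change of at least 2-fold was seen in 605 rising and 378 falling genes, and 1295 rising and 1428 falling genes were protein-coding. The 2 groups of values did not overlap in 34.8% of the tested genes, against 10% by chance. Fold changes are differences of mean log2(value + 1), so for low genes they can lie above or below the ratio of the group means. LAMB3 changed 49.9-fold on that scale against 2375% of control by the means, and STAB1 104-fold against 10964%. The other rising genes with the largest changes were LAMB3 (5.64), H2AC6 (4.66), MS4A14 (4.20), RHOB (4.19), KIAA0513 (4.00), H2BC21 (3.98), SEMA6B (3.56), TPSB2 (3.43), AKAP12 (3.42) and BBC3 (3.38). LAMB3, a laminin chain, had normalised read counts of 16.2, 0 and 0 in shCTRL replicates 1, 2 and 3 and 128 ± 15.7 (SD, n = 3) in shHASPIN, and DESeq2 did not call it (LAMB3 log2 fold change, adjusted p = 0.0692). TPSB2 and TPSAB1 are near-identical tryptase genes whose reads the counting can split, so the value of each is uncertain. MS4A14 and MS4A7, which also rose, overlap on the plus strand of chromosome 11. How reads in the shared stretch were counted is not given, so the single values of these 2 genes are uncertain as well. Other falling genes with large changes were CD180 (-4.27), CCN3 (-3.80), SIDT1 (-2.91), MACC1 (-2.89), CXADR (-2.87), GNG4 (-2.85), STRA6 (-2.78), SIRPG (-2.46), RASGRF1 (-2.28) and MMP16 (-2.28). CD180, a Toll-like receptor homologue, fell from 131 ± 103 (SD, n = 3) to 6.27 ± 5.17 (SD, n = 3), and MACC1 fell from 642 ± 191 (SD, n = 3) to 85.7 ± 24.7 (SD, n = 3). The 3' UTRs of KLF2 and CCN3 hold the word GTATTTA, those of ANAPC13, MACC1, CXADR and MMP16 hold TGTATTTA, and those of H2BC21, CD180, GNG4 and RASGRF1 hold TGTATTT. Without the mean-variance trend limma called 483 genes rising and 503 genes falling, and against shCTRL replicate 1 alone, an alternative chosen after the data were seen, 748 fell. Of the named genes 44 lost their call without the trend, 28 against shCTRL replicate 1 alone, and 1, 4, 21, 21, 9 and 24 without shCTRL replicates 1, 2 and 3 and shHASPIN replicates 1, 2 and 3. Rising and falling calls numbered 870 and 679 without shCTRL replicate 3, 790 and 859 without shHASPIN replicate 1, and 665 and 655 without shHASPIN replicate 3, while 2294 rose without shCTRL replicate 1 and 955 without shHASPIN replicate 2.

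**Figure D2:**
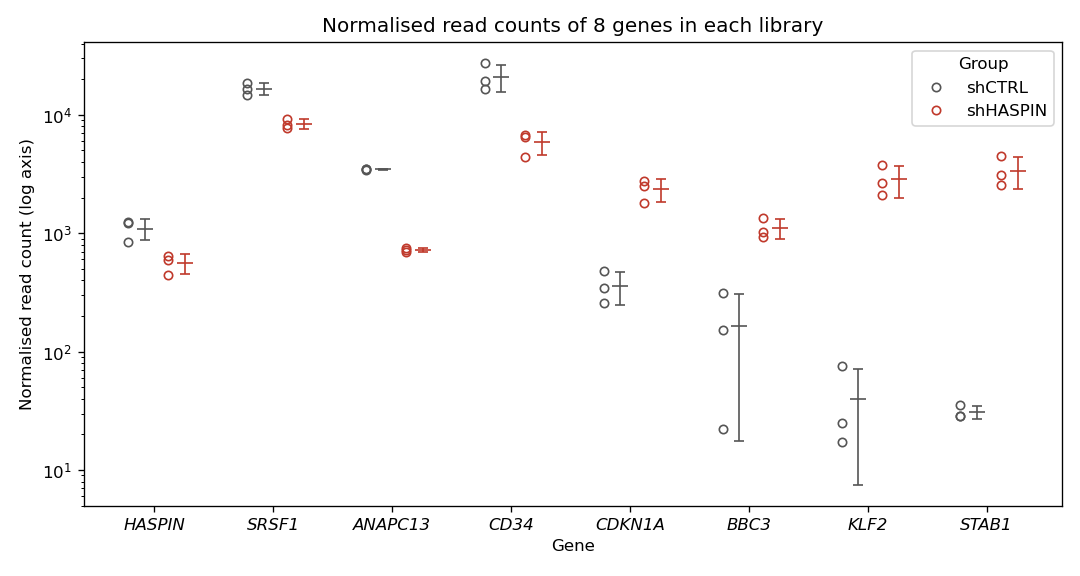
Normalised read counts (vertical log axis) of 8 genes in the 6 libraries, with open circles for single libraries and bars for the mean ± SD of each group (n = 3), grey for shCTRL and red for shHASPIN. HASPIN lay between 839 and 1234 in shCTRL and between 441 and 639 in shHASPIN, and the groups did not overlap for any gene drawn.

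The title of the series asks about splicing by SR proteins, the arginine- and serine-rich factors that help select splice sites. SRSF1 fell from 16566 ± 1949.7 (SD, n = 3) to 8384 ± 749.7 (SD, n = 3), to 50.6% of control (log2 fold change -0.98 ± 0.14 SE, limma adjusted p = 0.00116). SRSF10 fell by 0.60, SRSF2 by 0.53, SRSF3 by 0.51 and SRSF7 by 0.41 on the log2 scale. These 5 of the 12 measured SR proteins fell and the other 7 did not pass, with 6 falling when adjusted over the list alone. SRSF6 (-0.49, limma adjusted p = 0.0849), SRSF8 (-0.19), SRSF11 (-0.17), SRSF9 (-0.15), SRSF5 (-0.05), SRSF4 (-0.01) and SRSF12 (0.79) did not pass. The SRSF4 log2 fold change was 0.02 with equal library totals and 0.00 with quantile normalisation. The list was lower in the camera test with a median log2 fold change of -0.30 (adjusted p = 0.00336), a call lost at adjusted p = 0.369 with an estimated correlation. The 3' UTRs of SRSF2 and SRSF3 hold TGTATTT and GTATTTA, those of SRSF1, SRSF7 and SRSF10 hold neither word, and those of SRSF11 and SRSF12, which did not fall past the threshold, hold TGTATTTA. SRSF1 passed in each alternative run. The SRSF7 log2 fold change did not pass with equal library totals (adjusted p = 0.0607) or without shCTRL replicate 3 (0.13) or shHASPIN replicate 1 (0.168), 2 (0.0752) or 3 (0.136). Without shCTRL replicate 3 and without shHASPIN replicate 1, limma adjusted p was 0.0855 and 0.0915 for the SRSF10 log2 fold change, 0.0982 and 0.153 for the SRSF2 log2 fold change, and 0.0763 and 0.066 for the SRSF3 log2 fold change, and without shHASPIN replicate 3 it was 0.109 for SRSF2 and 0.0768 for SRSF3.

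The core spliceosome and hnRNP lists were lower too, and SR-related factors and nonsense-mediated decay genes did not pass as lists. In the core spliceosome 13 of 58 members fell, among them RBM8A (-1.24), SNRNP27 (-1.08), USP39 (-0.97) and SNRPF (-0.89), while SF3A2, named after its value was seen, rose by 0.49. That rise was lost without shCTRL replicate 3 or shHASPIN replicate 1, 2 or 3, and without the mean-variance trend. With DESeq2 and without shCTRL replicate 1, 2 members rose. The list was lower (camera adjusted p = 3.98e-05, median -0.21), with adjusted p = 0.369 with an estimated correlation, and 21 members fell and 2 rose when adjusted over the list alone. Of 26 hnRNP proteins, HNRNPR (-0.52), HNRNPC (-0.55) and HNRNPM (-0.44) fell, 2 of them when adjusted over the list alone. The hnRNP list had a camera adjusted p of 0.00326, and adjusted p = 0.449 with an estimated correlation. Among 24 SR-related factors and SR protein kinases, the kinase SRPK2 rose by 0.80 and TRA2B fell by 0.55, as did PNN (-0.46) and TRA2A (-0.45), the last 2 named after their values were seen. Adjusted over the list alone the counts were also 1 and 3, and the list did not pass (camera adjusted p = 0.443). Of 13 genes in the nonsense-mediated decay list NBAS alone passed, rising by 1.02, also when adjusted over the list alone (list camera adjusted p = 0.776). GADD45B, which that list also held though it is not a decay factor, had -0.48 without passing except after the GC and length fit. The 3' UTR of RBM8A holds TGTATTTA, that of TRA2B GTATTTA, and those of USP39, HNRNPR, HNRNPC and HNRNPM TGTATTT. Exon-level splicing was not analysed here. Without shCTRL replicate 3, shHASPIN replicate 1 or shHASPIN replicate 3, the SR proteins falling numbered 1, 1 and 2, and core spliceosome members 6, 7 and 6, while 20 of the latter fell without shCTRL replicate 1. SR proteins falling numbered 1 without the mean-variance trend, 1 against shCTRL replicate 1 alone and 3 with no filter on low values, and 6 with DESeq2, with the replicate block and without shCTRL replicate 1, SRSF6 among them, and the list median was -0.19 after the GC and length fit. Core spliceosome members falling numbered 6 without the mean-variance trend, 18 with the replicate block, 20 after the GC and length fit and 21 with DESeq2. Among SR-related factors limma called 0 falling without shCTRL replicate 3, shHASPIN replicate 1 or shHASPIN replicate 3 (4, 5 and 4 members at an unadjusted p under 0.05), 1 without shHASPIN replicate 2, and 5 falling and 3 rising without shCTRL replicate 1, and 2 decay genes rose without shCTRL replicate 2. For hnRNP proteins limma called 1 falling without shHASPIN replicate 1 and 0 without shCTRL replicate 3 or shHASPIN replicate 3, where 6 and 8 had an unadjusted p under 0.05. It called 0 hnRNP and 0 SR-related genes without the mean-variance trend (6 and 4 at an unadjusted p under 0.05), and the hnRNP proteins falling numbered 1 against shCTRL replicate 1 alone, 4 with edgeR, 5 with equal library totals, 5 after the GC and length fit, 7 with quantile normalisation and 7 with DESeq2.

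BCL-2 family genes were examined because the series title names a BCL-2 inhibitor. BCL2, the target of venetoclax, was 6993 ± 552 (SD, n = 3) in shHASPIN against 8563 ± 1801 (SD, n = 3) in shCTRL, a difference that did not pass (log2 fold change -0.27, limma adjusted p = 0.294), and the BCL2 log2 fold change was 0.09 against shCTRL replicate 1 alone. Among 5 measured anti-apoptotic members BCL2L1, which encodes BCL-XL, rose from 1727 ± 216 (SD, n = 3) to 2527 ± 71.8 (SD, n = 3) (log2 fold change 0.56, limma adjusted p = 0.0238). The call on the BCL2L1 log2 fold change was lost in limma without shCTRL replicate 2 (adjusted p = 0.0547) or 3 (0.0778), without shHASPIN replicate 1 (0.0776), 2 (0.0727) or 3 (0.0925), without the mean-variance trend (0.0871) and against shCTRL replicate 1 alone (0.173). MCL1 (0.34, limma adjusted p = 0.199), BCL2L2 (0.35) and BCL2A1 (0.62) did not pass in the main test. The MCL1 log2 fold change passed without shCTRL replicate 2 (0.54, limma adjusted p = 0.0203), after the GC and length fit (0.0382) and against shCTRL replicate 1 alone (0.62, adjusted p = 0.0315). Among 12 pro-apoptotic members 2 rose and 2 fell. BBC3, which encodes PUMA, rose from 313, 22.3 and 154 in the shCTRL replicates to 1098 ± 213 (SD, n = 3) (limma adjusted p = 0.00847; 0.102 for the BBC3 log2 fold change without the mean-variance trend), and BMF rose from 491 ± 131 (SD, n = 3) to 1538 ± 290.2 (SD, n = 3) (log2 fold change 1.66). PMAIP1, which encodes NOXA, fell from 3783 ± 855 (SD, n = 3) to 1640.2 ± 29.9 (SD, n = 3) (log2 fold change -1.18), and HRK fell by 1.70 on the log2 scale. BAX (0.24), BAK1 (-0.06), BOK (19.1 ± 17.5 (SD, n = 3) in shCTRL and 21.6 ± 11.9 (SD, n = 3) in shHASPIN), BCL2L11 (0.38), BAD (0.29), BID (-0.50), BIK (0.24) and BCL2L15 (-0.38) did not pass. Adjusted over the list alone, 1 anti-apoptotic member rose, and 2 pro-apoptotic members rose and 3 fell. BID passed with the replicate block, with DESeq2, after the GC and length fit and without shCTRL replicate 1, and BCL2L11 without shCTRL replicate 2, after that fit and against shCTRL replicate 1 alone. The fit without the mean-variance trend called 1 pro-apoptotic member rising, and without shCTRL replicate 1 BCL2 fell. Neither list passed (camera adjusted p = 0.276 and 0.862). The 3' UTRs of BCL2, BCL2L1 and MCL1 hold TGTATTTA, those of BCL2L2 and BCL2A1 hold TGTATTT, and those of HRK and BCL2L11 hold GTATTTA.

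**Figure D3:**
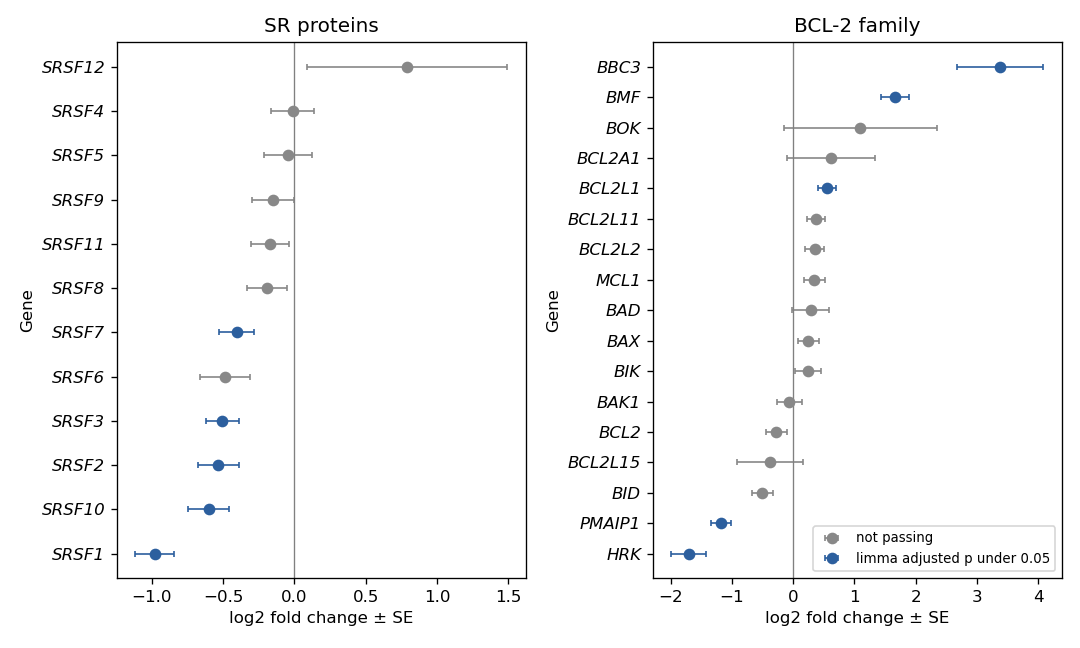
Log2 fold change ± SE (horizontal axis, shHASPIN over shCTRL, n = 3 per group) of the 12 SR proteins and of 17 BCL-2 family genes, with blue points at a limma adjusted p under 0.05 and grey points not passing. SRSF1 lies lowest among the SR proteins at -0.98, and the BCL-2 family runs from -1.70 for HRK to 3.38 for BBC3.

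Targets of p53 moved in both directions. CDKN1A, the cyclin-dependent kinase inhibitor p21, rose from 358 ± 112 (SD, n = 3) to 2359.6 ± 511 (SD, n = 3) (log2 fold change 2.74 ± 0.24 SE, limma adjusted p = 0.000107), and TP53INP1 rose by 2.04. In all 7 of 24 members rose and 4 fell, or 9 and 5 when adjusted over the list alone. The falling members were PMAIP1, TNFRSF10B (46.7% of control), DDB2 (-0.62) and MDM2 (-0.54), the last 3 named after their values were seen. The list did not pass (camera adjusted p = 0.324), and 2 members fell without shCTRL replicate 3, 2 without shHASPIN replicate 1, 2 without shHASPIN replicate 3 and 2 against shCTRL replicate 1 alone, while 4 rose and 2 fell without the mean-variance trend. The 3' UTR of TP53INP1 holds TGTATTTA.

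Genes of DNA replication and cell division were lower together, in 4 of the fixed lists. MCM10, a replication initiation factor, fell from 7821 ± 790.4 (SD, n = 3) to 2833 ± 220.5 (SD, n = 3) (log2 fold change -1.46 ± 0.13 SE, limma adjusted p = 0.000108). GINS4 fell by 1.25 and RFC3 by 1.14. Of 43 S phase genes 28 fell and 15 did not pass, with 36 falling and 1 rising when adjusted over the list alone. Of 25 DNA repair genes 15 fell, or 17 when adjusted over the list alone, including the checkpoint kinase CHEK1 (-0.96), XRCC2 (-0.93), TIPIN (-1.08) and FANCD2 (-0.99). Of 39 mitotic genes 15 fell, or 17 when adjusted over the list alone, including KIF11 (-0.64), CCNA2 (-0.64), CDC20 (-0.71) and AURKA (-0.54). The list of the HASPIN pathway and the centromere had 10 of 30 members falling, or 12 when adjusted over the list alone. They included CENPU (-0.73), the cohesin protector SGO1 (-0.76), CDCA8 (-0.64), a subunit of the chromosomal passenger complex, and CENPN (-0.64). The S phase list had a median log2 fold change of -0.59 (camera adjusted p = 2.66e-16), with adjusted p = 0.369 with an estimated correlation. DNA repair had a median of -0.52 (camera adjusted p = 1.51e-08), with adjusted p = 0.369 with an estimated correlation. The mitotic list had a median of -0.42 (camera adjusted p = 1.14e-06), with adjusted p = 0.369 with an estimated correlation. The centromere list had a median of -0.36 (camera adjusted p = 4.21e-06), with adjusted p = 0.176 with an estimated correlation. The 3' UTRs of GINS4, RFC3, XRCC2, TIPIN, KIF11 and AURKA hold TGTATTT or GTATTTA. Without shCTRL replicate 3, shHASPIN replicate 1 or shHASPIN replicate 3, the genes falling numbered 15, 16 and 15 in S phase, 4, 4 and 4 in DNA repair, 1, 3 and 4 in mitosis, and 3, 3 and 2 in the centromere list. Without the mean-variance trend they numbered 8, 3, 0 and 1, with 31, 16, 16 and 12 members at an unadjusted limma p under 0.05, against 28, 15, 14 and 10 called by edgeR and 32, 15, 17 and 12 by DESeq2. Against shCTRL replicate 1 alone they numbered 15, 3, 7 and 4, with medians of -0.54, -0.39, -0.42 and -0.50.

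**Figure D4:**
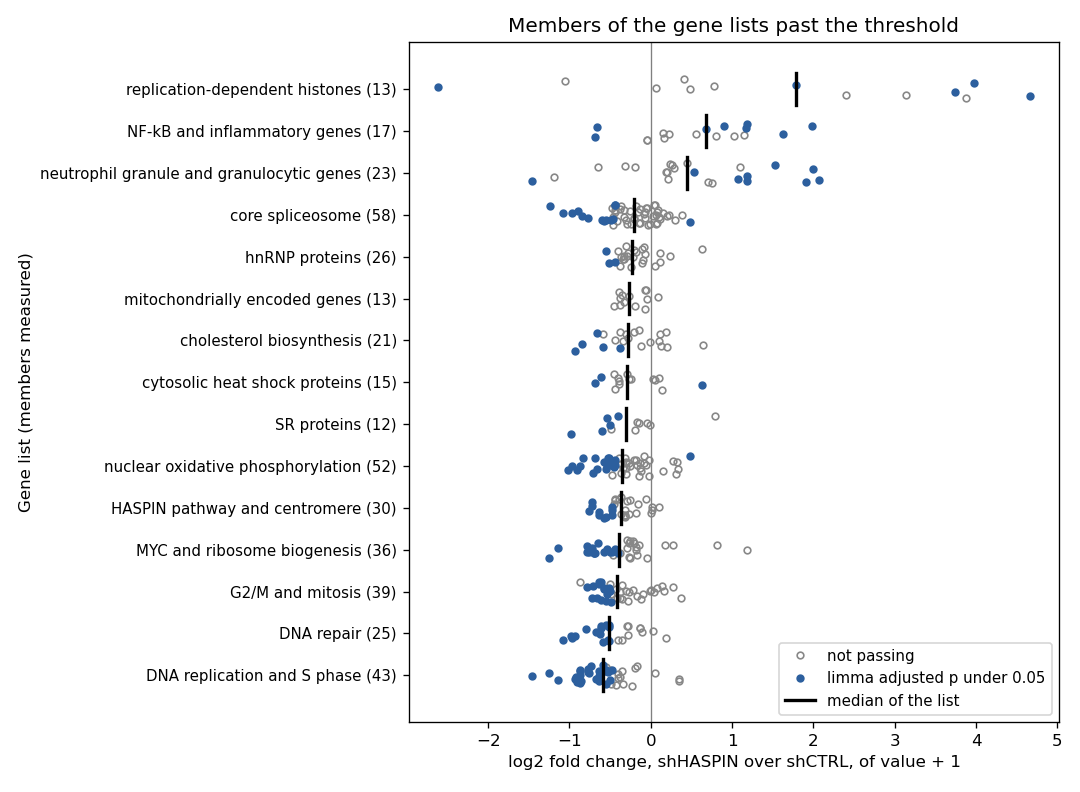
Log2 fold change (horizontal axis, shHASPIN over shCTRL) of each measured member of the 15 gene lists past the threshold, with the number of members in brackets, blue for a limma adjusted p under 0.05, open grey for not passing, and a black bar at the median. Medians run from -0.59 for S phase to 1.79 for the replication-dependent histones.

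Lists of MYC targets and ribosome biogenesis, of nuclear oxidative phosphorylation and of cholesterol synthesis were lower as well. DDX21, a nucleolar helicase, fell from 61949.6 ± 10393 (SD, n = 3) to 25872 ± 1769.9 (SD, n = 3) (log2 fold change -1.25, limma adjusted p = 0.000578), and its 3' UTR holds TGTATTTA. In the list of MYC targets and ribosome biogenesis 17 of 36 members fell, or 18 when adjusted over the list alone, including POLR1G (-1.14), NME1 (-0.79) and EBNA1BP2 (-0.75). The median was -0.39 (camera adjusted p = 1.51e-08), with adjusted p = 0.369 with an estimated correlation. Nuclear genes of oxidative phosphorylation had 19 of 52 members falling, including NDUFA4 (-1.01), NDUFAB1 (-0.97), SDHC (-0.90) and COX7A2 (-0.83), while COX7C, named after its value was seen, rose by 0.49. That rise was lost without shCTRL replicate 3 or shHASPIN replicate 1, 2 or 3, with no filter on low values and without the mean-variance trend. Without shCTRL replicate 1, 2 members rose. Adjusted over the list alone 25 fell and 1 rose, and the list had a median of -0.35 (camera adjusted p = 1.51e-08), with adjusted p = 0.369 with an estimated correlation. Cholesterol synthesis had 5 of 21 genes falling, the same number when adjusted over the list alone, including FDPS (-0.94), FDFT1 (-0.67) and MSMO1 (-0.59), and IDI1 (-0.38), named after its value was seen. That list had a camera adjusted p of 0.0103, and adjusted p = 0.449 with an estimated correlation. Cytosolic ribosomal proteins had RPL38 (-0.61) and FAU (-0.44) falling among 78. When adjusted over the list alone limma called 0 of them, with 8 at an unadjusted p under 0.05, and over all genes edgeR called 2 falling and DESeq2 3 falling and 1 rising. The ribosomal list did not pass (camera adjusted p = 0.805), and its median of 0.01 and its test direction, lower, differed in sign. Without shCTRL replicate 1, 13 ribosomal proteins rose, and against shCTRL replicate 1 alone the list was lower (camera adjusted p = 0.000792, median -0.18). Limma called 0 falling without shCTRL replicate 2 or 3 or shHASPIN replicate 1 or 3, with 4 members at an unadjusted p under 0.05 in each case, and 1 without shHASPIN replicate 2. With the replicate block 5 ribosomal proteins rose and 4 fell. SDHC holds TGTATTTA in its 3' UTR, FDFT1 holds GTATTTA, and MSMO1 and RPL38 hold TGTATTT. Members falling numbered 9 and 8 without shCTRL replicate 3 and shHASPIN replicate 3 in the MYC list, and 6, 7 and 6 without shCTRL replicate 3, shHASPIN replicate 1 and shHASPIN replicate 3 in oxidative phosphorylation. In cholesterol synthesis they numbered 2, 3 and 2 without shHASPIN replicates 1, 2 and 3. Without the mean-variance trend 6, 4 and 2 members of these lists fell, and against shCTRL replicate 1 alone 8, 15 and 3.

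Mitochondrially encoded genes and the list of cytosolic heat shock proteins were lower in the camera test, calls that many alternatives lost. HSPD1, a chaperonin of mitochondria that this list also held, fell from 74807 ± 4966 (SD, n = 3) to 46606 ± 3131 (SD, n = 3) (log2 fold change -0.68, limma adjusted p = 0.00541) and DNAJA1, a cytosolic co-chaperone, fell by 0.61, while BAG3, named after its value was seen, rose by 0.63. These were 3 of 15 members in the main test, also when adjusted over the list alone (camera adjusted p = 0.0481; adjusted p = 0.506 with an estimated correlation). Falling heat shock members numbered 4 without shCTRL replicate 2, where the median was -0.43, and 1 without shCTRL replicate 3 or shHASPIN replicate 3, and the rise of BAG3 was lost without shCTRL replicate 2 or 3 or shHASPIN replicate 1 or 3. HSPD1 and DNAJA1 hold TGTATTT and TGTATTTA in their 3' UTRs, and HSPA4L, which did not pass, holds TGTATTTA. HSP90AB1 (-0.44) and HSPA4L (-0.39) did not pass in the main test, and HSP90AB1 passed with equal library totals, the replicate block, DESeq2, the GC and length fit and without shCTRL replicate 1. Mitochondrially encoded RNA made up 6.69%, 6.33% and 6.19% of reads in the shCTRL replicates and 6.24%, 5.60% and 5.37% in the shHASPIN replicates. In the main limma test and with edgeR 0 of the 13 mitochondrially encoded genes passed, 3 passed with DESeq2, and 3 had an unadjusted limma p under 0.05. Limma called 2 of them falling with equal library totals, 2 without shCTRL replicate 1 and 1 with quantile normalisation. MT-CYB had -0.39, MT-ATP6 -0.45, MT-ND4 -0.38 and MT-CO2 -0.35. Their list had a median of -0.26, or -0.15 with quantile normalisation, -0.13 without shCTRL replicate 2 and -0.12 after the GC and length fit, and a camera adjusted p of 0.043, and adjusted p = 0.492 with an estimated correlation. With quantile normalisation the adjusted p was 0.146 for the mitochondrially encoded list and 0.135 for heat shock proteins, so neither passed, and after a fit of GC content and length, chosen after the data were seen, they were 0.404 and 0.0695. Without shCTRL replicate 3, shHASPIN replicate 2 or shHASPIN replicate 3 the mitochondrial list (0.0709, 0.063 and 0.116) and the heat shock list (0.169, 0.127 and 0.0656) were lost too, as were the mitochondrial list without shCTRL replicate 2 (0.0698) and the heat shock list without shCTRL replicate 1 (0.155). The heat shock list did not pass with edgeR (0.0594), DESeq2 (0.0592), equal library totals (0.0545), a pseudocount of 10 (0.0592), a mean of at least 50 (0.0894) or without the mean-variance trend (0.0951), nor the mitochondrial list with that pseudocount (0.0746), that mean (0.089) or against shCTRL replicate 1 alone (0.136).

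Myeloid granule genes were higher in the knockdown libraries. ELANE, neutrophil elastase, rose from 19248 ± 3338 (SD, n = 3) to 85264 ± 35803 (SD, n = 3) (log2 fold change 2.07 ± 0.26 SE, limma adjusted p = 0.000807), and AZU1 rose by 1.18 and CTSG by 1.07. NCF1 rose from 272 ± 97.3 (SD, n = 3) to 1061 ± 201 (SD, n = 3), with reads that its near-identical pseudogenes can share. Of 23 neutrophil granule and granulocytic genes 8 rose, and CEACAM6, named after its value was seen, fell by 1.46, with the same counts when adjusted over the list alone. The list had a median of 0.45 (camera adjusted p = 0.00682), with adjusted p = 0.369 with an estimated correlation. Of 19 monocyte and macrophage genes 5 rose and 1 fell, or 6 and 3 when adjusted over the list alone, including MS4A7 (2.99) and the receptor TLR2 (1.08), and LYZ (2.57), C1QB (2.17), CTSB (0.69) and CTSS (-0.59), the last 4 named after their values were seen. That list did not pass (camera adjusted p = 0.224). CD34, a progenitor surface marker, fell from 21048 ± 5435 (SD, n = 3) to 5889.9 ± 1291 (SD, n = 3) (log2 fold change -1.83), and the progenitor transcription factor HLF fell by 1.38. TAL1 (-0.51) fell, and NPR3 (1.16), GATA2 (0.81), LMO2 (0.74) and FLI1 (0.42) rose, all 5 named after their values were seen. In all 3 of 27 stem and progenitor genes fell and 4 rose, or 4 and 5 when adjusted over the list alone (camera adjusted p = 0.659, direction lower, with a median of 0.01 of the other sign). Among 19 genes associated with RUNX1-RUNX1T1, CCND2 fell by 1.25 and RUNX3 rose by 0.73, as did POU4F1 (0.62), while RASSF2 (-1.57) and TERT (-1.39) fell, the last 3 named after their values were seen. There 3 fell and 2 rose, or 4 and 4 when adjusted over the list alone (camera adjusted p = 0.998), and the median of 0.09 and the mean of -0.01 differed in sign. In their 3' UTRs CD34, HLF, CCND2 and MS4A7 hold TGTATTT, GTATTTA, TGTATTTA and TGTATTT. The neutrophil median was 0.29 with quantile normalisation and 0.24 after the GC and length fit. Without shHASPIN replicate 1 or 3, 5 neutrophil genes rose in each case, and without shHASPIN replicate 1, 3 monocyte genes rose. Limma called 0 monocyte genes falling without shCTRL replicate 3 or shHASPIN replicate 1, 2 or 3 (10, 10, 8 and 10 members at an unadjusted p under 0.05) and 2 without shCTRL replicate 2, and the list passed in camera with DESeq2 (adjusted p = 0.045), with no filter on low values (0.0493) and against shCTRL replicate 1 alone (0.0284). Without shCTRL replicate 1, 6 stem and progenitor genes fell and 4 RUNX1-RUNX1T1 associated genes rose, and 1 of the latter rose without shCTRL replicate 3 or shHASPIN replicate 1. The fit without the mean-variance trend called 4 neutrophil, 1 monocyte and 1 RUNX1-RUNX1T1 associated genes rising. Of the stem and progenitor genes it called 0 rising and 2 falling in limma, with 10 at an unadjusted p under 0.05, against 5 rising and 3 falling with edgeR and 5 and 5 with DESeq2.

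Inflammatory and histone transcripts made up the other higher lists. ICAM1, an adhesion molecule, rose from 953 ± 142 (SD, n = 3) to 2155 ± 187 (SD, n = 3) (log2 fold change 1.18, limma adjusted p = 0.00106), and TNF rose by 1.98, TNFAIP3 by 1.17 and RELB by 0.90. In all 6 of 17 NF-kB and inflammatory genes rose, while SOD2 (-0.68) and NFKBIE (-0.66), named after their values were seen, fell, with the same counts when adjusted over the list alone. The list had a median of 0.68 (camera adjusted p = 0.0445), with adjusted p = 0.369 with an estimated correlation. Replication-dependent histones, whose messages largely lack a poly-A tail, had 4 of 13 measured genes rising and H2BC9, named after its value was seen, falling by 2.61. H2AC6 rose from 14.1 ± 6.44 (SD, n = 3) to 366 ± 92.2 (SD, n = 3), H2BC21 by 3.98, H2BC5 by 3.74 and H2BC12 by 1.79, and 5 rose and 1 fell when adjusted over the list alone. The histone list had a median of 1.79 (camera adjusted p = 0.0338), with adjusted p = 0.449 with an estimated correlation. Mean deviations of that list from the mean of all libraries were 0.18, -0.86 and -1.82 in shCTRL replicates 1, 2 and 3, and 0.91, 0.87 and 0.72 in the shHASPIN replicates. With equal library totals neither list passed (adjusted p = 0.0537 for histones and 0.0545 for NF-kB), quantile normalisation gave 0.0529 for histones, and the fits without the mean-variance trend gave 0.0642 and 0.0658. ICAM1 and TNF, which rose, hold TGTATTTA in their 3' UTRs, and the GC and length fit gave 0.0799 for NF-kB. Without shHASPIN replicate 2 the values were 0.065 and 0.087, against shCTRL replicate 1 alone the histone list had 0.113 with a median of 0.64, and without shCTRL replicate 1 the NF-kB list had 0.169. Camera on ranks gave 0.064 for both lists and a mean of at least 50 gave 0.0578 for NF-kB, while the NF-kB median was 0.36 without shHASPIN replicate 1 and 0.42 without shCTRL replicate 2. The histone median was 0.71 with a pseudocount of 10, 0.74 with edgeR, 0.76 with DESeq2, 1.14 with quantile normalisation and 3.74 at a mean of at least 50, and 2 histone and 3 NF-kB genes rose without the mean-variance trend.

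The 3' UTR words named beside single genes came from a scan of 15529 words of 7 bases over 11569 genes, and were the 2 lowest words for these same fold changes, so the shares falling are not independent of that choice. Of the 1273 genes whose 3' UTR holds TGTATTTA, 28.5% fell, with a median log2 fold change of -0.24. The share falling was 19.5% among 967 genes with GTATTTA but not TGTATTTA, 14.1% among 2180 genes with TGTATTT but not GTATTTA, and 7.39% among 7149 genes with neither word, whose median was 0.07. In the HASPIN transcript TGTATTT occurs 1 time, in the coding part, at transcript positions 1355 to 1361 (chromosome 17, 3725257 to 3725263, GRCh38). GC content also differed, with a median of 55.0% in rising and 44.1% in falling genes against 49.1% in all tested genes. Genes were ordered by GC content into 4 classes, and the median log2 deviation of the highest class minus that of the lowest was 0.13, -0.46 and -0.20 in shCTRL replicates 1, 2 and 3, and 0.15, 0.35 and 0.06 in the shHASPIN replicates.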

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

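The GC and length fit and the use of shCTRL replicate 1 as the only control were chosen after the data were seen, and the other alternatives were planned. EdgeR called 1421 genes rising and 1507 genes falling, of which 1390 and 1467 were called by limma too, and DESeq2 called 1906 and 2028. After the GC and length fit 1843 rose and 1999 fell. Without the mean-variance trend, which gives all genes the same prior spread, 483 rose and 503 fell, 1 list was higher, and the HASPIN transcript level kept -0.96 with an adjusted p of 0.0754 in limma. At a log2 fold change of at least 1 the counts were 605 and 378. Lists higher numbered 5 with no filter on low values, 1 with equal library totals and 1 with camera on ranks, and the cause was not tested. With an estimated correlation camera called 0 lists higher and 0 lower, and 3 had an unadjusted p under 0.05. The estimates were 0.54 for S phase, 0.32 for the MYC list and 0.22 for DNA repair, well above the small preset value. A higher correlation makes camera stricter. The estimates were -0.0022 for the centromere list and -0.0168 for the neutrophil list, and these calls were lost too. For these lists the cause was not tested. Against shCTRL replicate 1 alone, with fewer samples, 748 fell, 5 lists were higher, and HASPIN was -0.60 (limma adjusted p = 0.179, range over alternatives 0.000252 to 0.179), where the lone control was assumed to vary like the knockdown group. Leaving out each library in turn gave 665 to 2294 rising and 655 to 2033 falling genes, 1 to 5 lists higher, 10 to 12 lists lower, and -1.14 to -0.80 for HASPIN. Of the comparisons of named genes over all alternatives 2343 kept their direction and side of the threshold, 162 lost a call, 42 gained a call, and 20, none of them past the threshold, changed sign, with 44 of the losses in the fit without the trend. The smallest share recovered in simulated data was 18.0% at 1.5-fold, with 200 changed genes in each run, where small changes were often missed. Other depths and larger numbers of changed genes were not simulated, so the share missed in the real data is not known.

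The groups share replicate numbers, and same-numbered libraries carry the same number tag in their descriptions, but the labels do not say that a number or tag marks a shared culture or day. Deviations of same-numbered libraries from their group means correlated at 0.141, 0.0949 and 0.0171 for replicates 1, 2 and 3. The libraries of replicates 1 and 2 correlated best with their own number, as did shHASPIN replicate 3 (0.0171). For shCTRL replicate 3 the values were nearly the same with shHASPIN replicate 2 (0.0173) and with its own number (0.0171). With the replicate block limma called 2089 genes rising and 1884 genes falling, and 4 lists were higher and 12 lower.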

Other observations

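The tests of AU-rich words, of read totals, of amplified copies within libraries, of the GC and length fit and of shCTRL replicate 1 as the only control were chosen after the results were seen. Among stress and metabolic lists that did not pass as groups, 2 held genes moving in both directions and the endoplasmic reticulum chaperone list held rising genes. Interferon-stimulated genes moved in both directions too. Of 27 ATF4 and amino acid response genes 6 rose and 9 fell (camera adjusted p = 0.199), or 7 and 9 when adjusted over the list alone. The serine synthesis enzyme PSAT1 fell from 11288 ± 1367 (SD, n = 3) to 4069 ± 270.2 (SD, n = 3) (log2 fold change -1.47), and SESN2 rose by 1.20. Falling members of that list numbered 2, 3 and 1 without shCTRL replicate 3, shHASPIN replicate 1 and shHASPIN replicate 3, and the list was lower after the GC and length fit (camera adjusted p = 0.0399, median -0.19). Of 20 members of the endoplasmic reticulum chaperone list 5 rose, also when adjusted over the list alone (camera adjusted p = 0.125). They were SYVN1 (0.92) and DNAJB9 (0.96), and CRELD2 (0.81), HERPUD1 (0.91) and HSP90B1 (0.54), the last 3 named after their values were seen. The list also held SYVN1 and HERPUD1 though they are not chaperones. The chaperone list passed in camera with quantile normalisation (adjusted p = 0.0358), without shCTRL replicate 2 (0.0103) and against shCTRL replicate 1 alone (0.000263), and 2 and 1 members fell without shCTRL replicates 1 and 2. Among 30 glycolysis and hypoxia genes 6 rose, led by ADM (1.87) and DDIT4 (2.27), and 7 fell, or 7 and 9 when adjusted over the list alone (camera adjusted p = 0.625), and the median of -0.11 and the mean of 0.03 differed in sign. Falling members of that list numbered 4 without shCTRL replicate 3, 1 without shHASPIN replicate 1, where 3 rose, and 0 in limma without shHASPIN replicate 3, where 15 members had an unadjusted p under 0.05. Of 37 interferon-stimulated genes 4 rose and 3 fell, or 5 and 3 when adjusted over the list alone, with OAS1 (-1.54), OAS3 (-0.88) and EPSTI1 (-2.54) falling and IFIH1 (1.02), IFI44 (204% of control), IRF7 (0.91) and CMPK2 (0.55) rising, the last 5 named after their values were seen (camera adjusted p = 0.715). Without shCTRL replicate 2 or shHASPIN replicate 1, 2 interferon-stimulated genes rose, and without shHASPIN replicate 3 limma called 0 rising, with 9 members at an unadjusted p under 0.05. Without the mean-variance trend 2 ATF4 genes rose and 1 fell, and 3 members of the chaperone list rose. In that fit 1 interferon-stimulated gene rose and 2 fell, and 1 glycolysis gene rose, while 7 interferon-stimulated genes rose with DESeq2.

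Marker lists of other cell types did not pass in camera under the main test. Of 10 mast cell, basophil and eosinophil genes TPSAB1 (3.33) and TPSB2 rose, near-identical genes whose single values are uncertain (camera adjusted p = 0.0782), and the list passed without shCTRL replicate 2 (0.0307), against shCTRL replicate 1 alone (0.0248), at a mean of at least 50 (0.0379), with no filter on low values (0.0493) and with the replicate block (0.0345). Of 6 erythroid genes TFR2 (-0.88) and SLC4A1 (-3.65) fell (camera adjusted p = 0.126), and of 7 B cell genes CD22 (-1.20) and IGLL1 (-1.08) fell (camera adjusted p = 0.129). Of 8 megakaryocyte and platelet genes GP6 rose by 2.07 and GP1BA fell by 1.06 (camera adjusted p = 0.281). Of 8 T and natural killer cell genes CD3E fell from 64.4 ± 17.8 (SD, n = 3) to 2.63 ± 0.798 (SD, n = 3), and NKG7 had -1.18 without passing (camera adjusted p = 0.243). In these 5 lists the counts were the same when adjusted over the list alone. Falling erythroid genes numbered 1 without shCTRL replicate 3, shHASPIN replicate 2 or shHASPIN replicate 3, and falling B cell genes 1 without shCTRL replicate 3 or shHASPIN replicate 1 and 0 in limma without shHASPIN replicate 3 (2 members at an unadjusted p under 0.05). Limma called 0 megakaryocyte genes falling without shCTRL replicate 1 or 3 or shHASPIN replicate 1 or 3 (2, 3, 4 and 3 members at an unadjusted p under 0.05), and 2 T and natural killer cell genes fell without shCTRL replicate 2. Fitted without the mean-variance trend, 1 mast cell gene rose, and limma called 0 erythroid, 0 B cell and 0 megakaryocyte genes falling (2, 3 and 3 at an unadjusted p under 0.05), against 1, 2 and 1 with edgeR and 2, 2 and 1 with DESeq2. In the fibroblast (10 measured), epithelial (6) and MHC class II (9) lists limma and edgeR called 0 genes, DESeq2 called 1, 0 and 0, and 3, 0 and 2 had an unadjusted limma p under 0.05, while 1 MHC class II gene rose without shCTRL replicate 1. NKG7 passed with the replicate block and without shCTRL replicate 2, PDGFRA with that block and DESeq2, THY1 with that block and against shCTRL replicate 1 alone, CIITA with that block and without shCTRL replicate 1, and CD74 with quantile normalisation. DNAJB9, OAS3, CD3E and PDGFRA hold TGTATTT in their 3' UTRs. The leading values of the fibroblast, epithelial and MHC class II lists were PDGFRA (1.36), THY1 (-0.94), CLDN4 (1.06), MUC1 (0.50), CIITA (0.45) and CD74 (0.30), with camera adjusted p of 0.634, 0.791 and 0.689.

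Several falling genes fell far and with little spread, ANAPC13 from 3463 ± 30.6 (SD, n = 3) to 720.3 ± 30.3 (SD, n = 3). An effect shared by all words ending in TATTTA is argued against, since the other 3 had z values of 0.42 or higher against -11.8 for GTATTTA. The GC content of 3' UTRs was fitted before the scan, so these z values cannot tell of AU-rich 3' UTRs in general. GC content and length as the whole cause are argued against by the 90.9% of falling calls kept after their fit. A hypothesis that stays open is that the hairpin lowered part of these genes through seed matches in their 3' UTRs: TGTATTT, which the HASPIN transcript holds, had z = -8.8, against -4.46 as the lowest in 100 shuffles. Genes with TGTATTT but not GTATTTA had a mean remainder after the length and GC fit of -0.00446 ± 0.0124 (SE). It was 0.0455 ± 0.00652 (SE) with neither word and -0.186 ± 0.0166 (SE) with TGTATTTA. TGTATTT alone thus went with a small lowering, in the direction of the hypothesis, and its z rests mainly on genes that also hold GTATTTA. GTATTTA itself is not in the HASPIN transcript, where the place reads TGTATTTG. Without the hairpin sequence it is not known which of these bases would pair, so that absence does not count for or against the hypothesis. A given word of 7 bases occurs by chance in 15.7% of transcripts of the length of HASPIN. That share holds for a word named beforehand, whereas TGTATTT was picked from the lowest words after the scan. A match of some low word is therefore more likely than 15.7%. Among other words that passed the shuffles, the transcript holds AGTATTT (z = -6.07) and TACAGGC (z = -5.60). It lacks others, such as GGATTAC (z = -5.65), and without the hairpin sequence the match could not be checked.

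The lower number of genes detected in shCTRL replicates 2 and 3 was the next pattern. Fewer reads are argued against, since replicate 2 held 70.0 M reads, within the range of the other libraries. Amplified copies of few starting molecules may account for it: the genes with 5 reads per gene with 1 read were at least 1.29 in both and at most 0.700 in the other 4. No biological explanation was tested.

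The cell division lists were lower as a block, with 68 of the 137 members of the S phase, DNA repair, mitosis and centromere lists falling. With an estimated correlation the 4 lists did not pass in camera (adjusted p = 0.369, 0.369, 0.369 and 0.176), and members falling numbered 15, 4, 1 and 3 without shCTRL replicate 3, 16, 4, 3 and 3 without shHASPIN replicate 1, 15, 4, 4 and 2 without shHASPIN replicate 3, and 8, 3, 0 and 1 in limma without the mean-variance trend (31, 16, 16 and 12 at an unadjusted p under 0.05; 32, 15, 17 and 12 called by DESeq2). The 2 words of the scan as the whole cause are argued against by the 98 members with neither word, whose median log2 fold change was -0.44 (quartiles -0.63 and -0.25). The same holds for GC content and length, with a median of -0.41 after the fit, and for amplified copies in shCTRL replicates 2 and 3, with -0.44 against replicate 1 alone. Seed matches other than these words could not be tested without the hairpin sequence. They, the knockdown of HASPIN, an off-target gene and a difference between cultures stay open and were not tested.

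The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 1515 rising and 1530 falling genes with limma and the highest other gave 0, with at most 1293 genes at an unadjusted p under 0.05, so 1 split of 10 was as large in each direction. For gene lists the real split gave 3 higher and 12 lower and the highest other gave 9, so 10 and 1 of the 10 splits were as large.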
